A study of Homo sapiens with 2 samples.

How the data were processed

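Poly(A) RNA of MCF7 and T47D was measured by RNA-seq in 4 libraries, 2 per line. Per the labels' protocols, both lines grew in the same medium without treatment, poly(A) RNA was selected on oligo(dT) beads in 2 rounds, and libraries were made with the NEBNext kit. Library 1 of each line carried custom 4 bp barcodes and was sequenced on a GAIIx as 32 bp single reads. Library 2 of each line carried standard indexed primers and was sequenced on a HiSeq 2000 as 42 bp single reads. The samples were grouped by cell line, and the labels do not say whether the libraries of a line came from separate cultures.

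The deposited table lists 11472 genes by Ensembl ID, RefSeq accession and symbol, with 1 column per library. The submitters' processing notes name TopHat 1.3.3, HTSeq 0.5.3p3, edgeR 2.6.12 and genome build hg18, without saying which step each served. The values of the authors are a signal per gene, namely pseudo-counts moved to a common library size, and not whole counts. Their column totals lay between 6750345 and 7390615. The authors' deposited table also gives a log2 fold change of T47D over MCF7 and a p-value per gene, for which no source used here states an adjustment. How genes were chosen for the table is not given in the sources used here, and the lowest value of the higher line's mean was 15.3 pseudo-counts. Whether counting used the strand is not stated, so that reads of overlapping genes cannot be told apart. No coordinates are given, because the annotation at hand is of another build.

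The pseudo-counts were turned back into reads by inverting the negative binomial quantile adjustment that gives them. The relative library sizes and a common dispersion of 0.0592 were found from low values that repeat. Within a tolerance of 0.1 reads, 99.998% of the values came out whole and 1 value did not. Tested on simulated data of 11472 genes, the procedure recovered 100% of the reads. The reads summed to 4038572 in MCF7 library 1, 16391086 in MCF7 library 2, 3235248 in T47D library 1 and 11045078 in T47D library 2, over the genes of the table only. The median gene had 160 reads in MCF7 library 1, 626.5 in MCF7 library 2, 127 in T47D library 1 and 394 in T47D library 2, so the libraries numbered 2 are the more precise. The 20 most abundant genes held 5.94% to 7.27% of the reads of a library. Reads were used for depth, floors, ratios of genes with few reads and an alternative test, and the main test used the pseudo-counts.

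The main test was limma 3.58.1 in R 4.3.3 on log2(pseudo-count + 1), with a trend of the variance with the mean and cell line as the only term. All 11472 genes were tested, and p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. The design fixed before the data were examined named this test for a table of normalized values, in place of a quasi-likelihood test on counts. That count test, its TMM factors, an exact test and a Wald test were not run, neither on the deposited values, which are not counts, nor on the recovered reads, which were tested with limma's voom only. Folds are ratios of mean pseudo-counts. A line with 0 reads in both libraries was set to the worth of 3 reads over both libraries, and the fold is then a lower bound. With 1 to 3 reads, the ratio of reads per relative library size is given with an exact 95% interval. Of 137 genes under the naming rule that passed, 43 had a fold, ratio or bound that moved by over 1.5 times without 1 library. For those given with levels or a fold in the report, the value without it is given. Bounds were recomputed without libraries of the higher line only. Intervals and floors cover counting error only.

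Gene lists were fixed before the data were examined. Of 879 entries in 30 lists, 618 were matched to a row, by Ensembl ID or else by current or older symbol. A table of gene names held 11227 of the table's IDs, 9589 of them under the same symbol. An ID match was dropped where the row carried the symbol of another gene, which removed 3 entries (IRF9, UGT1A6 and AHRR). That rule was set after list results had been seen. It left 40 members in the interferon list and 18 in the steroid and xenobiotic list, and the number of lists that passed stayed the same. The 27 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists. The estimated correlation and its test rest on the few residual degrees of freedom that 4 libraries leave. Such a test can hardly pass, so its adjusted p does not decide whether correlation between genes accounts for a list's call. List medians were the same to the digits printed when genes without reads in a line were set at their bounds.

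Genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest log2 fold changes in each direction among genes that passed, had at least 10 CPM (pseudo-counts over their column total) in the higher line and did not overlap between the lines, leaving out sex-linked marker genes. It adds 15 genes of prior interest, and from each list up to 4 members that passed, by smallest p, with up to 2 in the minority direction. Of the 144 genes it gives, most are named. Zinc finger genes and region ends in the closing observations were chosen after their values were seen.

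Across genes, the libraries of a line had a Pearson correlation of log2(pseudo-count + 1) of 0.958 in MCF7 and 0.952 in T47D, and those of different lines had 0.646 to 0.699. Each library number stands for a construction and sequencer shared by both lines, so it pairs the libraries by the labels. The deviations of same-numbered libraries from their line's mean had a correlation of 0.417 across genes. A fit with the library number as a block is given where it changes a call or moves a count by over 1.5 times. Other alternatives were 4 scalings, 2 filters on low values, pseudocounts of 0.1 and 5, limma's voom on the recovered reads, comparison within each library type and leaving out each library in turn. With a library left out, the lone library of its line is assumed to vary like those of the other line.

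The main test was checked on simulated data of 11472 genes, drawn at the real means and library sizes for MCF7 against T47D, in which 200 genes differed. It recovered 26% of the 2-fold and 93% of the 4-fold differences with 7 false calls, and with the library number as a block 28% and 93% with 11 false calls. The simulated libraries were drawn independently, without the effect that libraries of the same number share in the real data, so these shares do not show what the block does there, and the lists were simulated without correlation between genes. Simulated values were reads divided by the relative library size, without the quantile adjustment that ties the pseudo-counts of a line's libraries to each other. The false calls therefore do not check the test on pseudo-counts. Only 200 of 11472 simulated genes differed and all shared 1 dispersion, whereas 3308 genes passed in the real data. A larger number of differences loosens the adjusted threshold, so the recovered shares are not the power of the test there. Camera found a simulated list of 30 genes raised 1.5-fold with adjusted p = 8.9e-12 and called 0 of 50 unchanged lists. Gene order for the closing observations was taken from GENCODE release 29, in which 11232 of the genes had a place, and was used only for which genes neighbour each other. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.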

Results

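Poly(A) RNA was sequenced from MCF7 and T47D, human breast cancer cell lines that express the estrogen receptor, both kept under standard growth conditions without treatment. Each line was represented by 2 libraries. Library 1 of each line carried custom 4 bp barcodes and was read as 32 bp single ends on a GAIIx, and library 2 carried standard indexed primers and was read as 42 bp single ends on a HiSeq 2000. The deposited table gave 1 value per library for each of 11472 genes, as pseudo-counts at a common library size. Reads recovered from these values summed to 4038572 and 16391086 in MCF7 libraries 1 and 2, and to 3235248 and 11045078 in T47D libraries 1 and 2. A gene with 0 reads in both libraries of a line could still hold up to 1.02 pseudo-counts in MCF7 and 1.52 in T47D, the worth of 3 reads over both libraries. These floors and the intervals given for ratios cover counting error only. No source states that the libraries of a line came from separate cultures, so the p-values per gene measure only the spread between libraries, which may be technical. The only comparison the design gives is MCF7 against T47D, and every log2 fold change is MCF7 minus T47D on the log2(pseudo-count + 1) scale, which understates changes of low genes.

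The question was which genes the lines express at different levels when no treatment is given. By limma's moderated test on log2 values, the lines differed in 3308 of 11472 genes, of which 1596 were higher in MCF7 and 1712 were higher in T47D. At least a 2-fold change was seen for 3081 of them. Genes that passed included some that were abundant in either line with almost no reads in the other. SERPINA6, which encodes the corticosteroid-binding globulin (ENSG00000170099), averaged 9.38 ± 12.003 pseudo-counts in MCF7 and 22078 ± 9877 in T47D, all values as mean ± SD over n = 2 libraries. PIP, the prolactin-induced protein secreted by apocrine cells (ENSG00000159763), averaged 1.73 ± 2.11 pseudo-counts in MCF7 and 3879.9 ± 1439.9 in T47D. AZGP1, another secreted apocrine product (ENSG00000160862), averaged 2.22 ± 0.508 pseudo-counts in MCF7 and 2724 ± 436 in T47D. The adjusted p was 0.00016 for SERPINA6, 7.1e-05 for PIP and 3.2e-05 for AZGP1. The iron exporter gene SLC40A1 (ENSG00000138449) was 899-fold higher in T47D, and the calcium channel gene TRPV6 (ENSG00000165125) was 876-fold higher. ABCC11, an efflux transporter of apocrine glands, was 689.5-fold higher in T47D and OLFML3 was 572-fold higher. The contractile and actin-binding genes MYL9 and CNN3 belonged to the same group. MYL9 had 3 reads in MCF7 and 4301 in T47D, a ratio of 2138 (exact 95% interval 731 to 10372), and CNN3 averaged 2.23 ± 2.73 pseudo-counts in MCF7 and 2253 ± 5.58 in T47D. No read of GNG11 or SPINK5L3 was recovered from MCF7, which put them at least 776-fold and 1071-fold higher in T47D, with adjusted p = 7.3e-05 and 0.00020. Without MCF7 library 1, the fold was 483 for SLC40A1 and 472 for TRPV6. Without T47D library 1, the lower bounds were 463 for GNG11 and 305 for SPINK5L3, and the latter was 1838 without T47D library 2. The folds of SERPINA6, PIP and CNN3, 2354, 2239.6 and 1011 over all libraries, were 1236, 1203 and 542 without MCF7 library 1, and that of SERPINA6 was at least 4372 without MCF7 library 2.

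The genes most raised in MCF7 had similar ranges. WIPF1, whose product binds the actin regulator WASP (ENSG00000115935), had 4569 reads in MCF7 and 2 in T47D, a ratio of 1532 (exact 95% interval 424 to 12653). TFPI, the inhibitor of the tissue factor pathway of coagulation (ENSG00000003436), had 1886 reads in MCF7 and 1 in T47D, a ratio of 1265 (exact 95% interval 227 to 49977). CXCR7, a chemokine receptor (ENSG00000144476), averaged 3618 ± 777 pseudo-counts in MCF7 and 14.7 ± 18.4 in T47D. BASP1 averaged 1818 ± 883 pseudo-counts in MCF7 and 4.55 ± 5.41 in T47D, and CYBA, a subunit of the NADPH oxidase, averaged 1963 ± 814 pseudo-counts in MCF7 and 6.40 ± 7.71 in T47D. SYTL5 and ADAMTS19 were 509-fold and 421-fold higher in MCF7. ADCY5, an adenylate cyclase, had 1749 reads in MCF7 and 2 in T47D, and the kinase gene DCLK1 had 995 and 1. The protocadherin gene PCDH10, the caveolin gene CAV1 and NT5E, which encodes the ecto-nucleotidase CD73, had no reads in T47D, so that they were at least 618-fold, 231-fold and 261-fold higher in MCF7. The adjusted p of these genes lay between 7.1e-05 for WIPF1 and 0.00052 for CXCR7. Each of these genes, as well as SNRPN among the imprinted genes, passed the test with any 1 of the 4 libraries left out, and together they were the 12 largest differences in each direction among genes that passed, with at least 10 CPM in the higher line and no overlap between the lines, sex-linked marker genes left out. The size of several differed between library types. CXCR7 had a log2 fold change of 10.61 between the libraries numbered 1 and 6.74 between those numbered 2, and SERPINA6 had -12.96 and -10.59. No read of CXCR7 was recovered from T47D library 1 and none of SERPINA6 from MCF7 library 1. Their pseudo-counts there, 1.67 and 0.892, were set by the quantile adjustment and lay under the worth of 3 reads (6.26 and 5.05). The log2 fold changes between the libraries numbered 1 are therefore uncertain for both genes, and so is the size of each gap. Over 26 genes abundant in MCF7 and under 1% of that level in T47D, CXCR7 among them, T47D library 2 held 0.606% of the MCF7 level and library 1 held 0.157%. Over 36 such genes of T47D, SERPINA6 among them, MCF7 library 2 held 0.445% and library 1 held 0.290%, so that low levels of this size limit the folds printed. Without T47D library 1, the fold was 279 for SYTL5 and 232 for ADAMTS19. Without MCF7 library 1, the lower bounds were 147 for PCDH10, 141 for CAV1 and 90.7 for NT5E, and without MCF7 library 2 those of PCDH10 and NT5E were 1089 and 430.4. The folds of CXCR7, BASP1 and CYBA, 246, 399 and 307 over all libraries, were 131, 217 and 166 without T47D library 1. That of CXCR7 was at least 578 without T47D library 2 and that of BASP1 was 262 without MCF7 library 2. Without MCF7 library 2 the ratio of reads was 2922 (exact 95% interval 808 to 24146) for WIPF1, 2698 (exact 95% interval 483 to 106680.0) for TFPI and 1478 (exact 95% interval 264 to 58524) for DCLK1.

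Library types 1 and 2 gave the same direction for 83.2% of all genes. The log2 fold changes of the library types had a Pearson correlation of 0.923 across genes, which are not independent replicates. With the library number as a block, 5801 genes passed, 2909 higher in MCF7 and 2892 higher in T47D, and all 3308 genes were among them. That fit borrows most of its spread from other genes (moderated degrees of freedom 22.6, against 7.74 in the main fit), so its added calls are less certain. Without MCF7 library 1, MCF7 library 2, T47D library 1 or T47D library 2, the count was 1298, 1458, 1614 or 1530, and 1053 genes passed in all 4 of these fits. In the authors' deposited table, 4669 genes had a p-value under 0.05, with no statement of whether it was adjusted. It held 11405 distinct p-values over 11472 genes. Adjustment after Benjamini and Hochberg would give more repeats, which argues against that adjustment. Once so adjusted here, 3715 genes were under 0.05, and in the main test 4655 genes had an unadjusted p under 0.05. All 3308 genes had the authors' direction, which is no separate support, because those values come from the same libraries.

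Among the hormone receptors, PGR, the progesterone receptor gene (ENSG00000082175), averaged 149 ± 58.4 pseudo-counts in MCF7 and 4539 ± 2663 in T47D (log2 fold change -4.84, SE 0.46, adjusted p = 0.00033). ESR1, the estrogen receptor gene, averaged 3356 ± 434 pseudo-counts in MCF7 and 2342 ± 500.1 in T47D and did not pass (log2 fold change 0.53, adjusted p = 0.20), while it passed with the library number as a block (adjusted p = 0.047). AR averaged 287 ± 118 pseudo-counts in MCF7 and 404 ± 171 in T47D (adjusted p = 0.41), and ERBB2 averaged 1475 ± 523 pseudo-counts in MCF7 and 1439 ± 82.5 in T47D (adjusted p = 0.98). The transcription factor genes GATA3 and FOXA1, which work with the estrogen receptor in luminal cells, had log2 fold changes of 0.32 (SE 0.35, adjusted p = 0.52) and -0.31 (SE 0.25, adjusted p = 0.38). None of AR, ERBB2, GATA3 and FOXA1 passed with the library number as a block. CDKN2A, the p16 and ARF locus (ENSG00000147889), averaged 9.79 ± 3.50 pseudo-counts in MCF7 and 385 ± 21.03 in T47D (adjusted p = 0.00017). Its neighbour MTAP, a methionine salvage enzyme gene, was 6.50-fold lower in MCF7 (adjusted p = 0.0022). The anti-apoptotic gene BCL2 averaged 608 ± 278 pseudo-counts in MCF7 and 14.1 ± 11.2 in T47D (adjusted p = 0.00058). TP53 was 1.91-fold higher in MCF7 (adjusted p = 0.039), CCND1, the cyclin D1 gene, was 2.21-fold higher (adjusted p = 0.039), and CASP3, the caspase-3 gene, was 2.39-fold lower (adjusted p = 0.043). The calls for TP53, CCND1 and CASP3 were lost without any 1 of the 4 libraries, with adjusted p = 0.080 to 0.24, 0.11 to 0.27 and 0.11 to 0.27. The call for CASP3 was also lost with scaling by the totals, or by the totals without the 20 most abundant genes. Without T47D library 1, the fold of PGR was 17.8 in place of 30.4 and that of BCL2 was 27.6 in place of 43.3. Without T47D library 2, that of BCL2 was a ratio of reads of 118 (exact 95% interval 32.6 to 975).

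**Figure D1:**
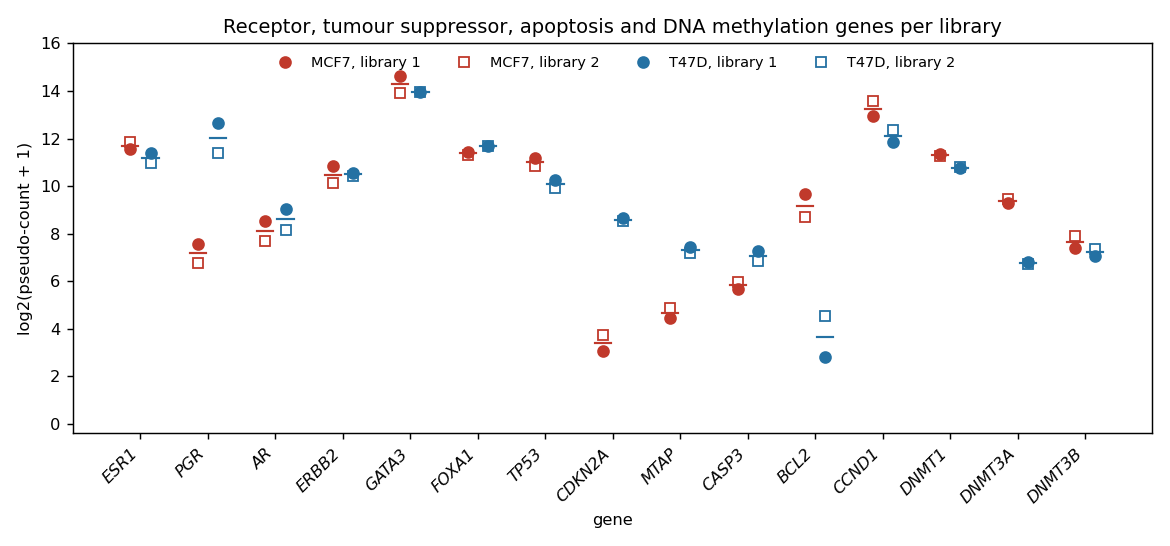
Values of 15 genes chosen before the data were examined, as log2(pseudo-count + 1) on the vertical axis, with 1 symbol per library and short lines for the mean of the 2 libraries of a line. PGR, CDKN2A and MTAP lay higher in both T47D libraries and BCL2 and DNMT3A in both MCF7 libraries, while the lines overlapped for AR, ERBB2 and GATA3.

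Interferon-stimulated genes were higher in MCF7 as a group. Of 40 measured members, 35 were higher in MCF7, none was lower and 5 did not pass, and 36 passed when adjusted over the list alone. ISG15, a ubiquitin-like modifier (ENSG00000187608), averaged 7313 ± 3408 pseudo-counts in MCF7 and 146 ± 58.1 in T47D. The membrane antiviral factor IFITM3 was 51.4-fold higher in MCF7 and IFI6 was 30.2-fold higher, with adjusted p = 0.00012 and 0.00013. IFI44L had 1444 reads in MCF7 and 2 in T47D, a ratio of 484 (exact 95% interval 134 to 4001). The set test camera, which compares a list with all other genes, gave adjusted p = 6.2e-21 with its preset correlation and adjusted p = 0.26 with an estimated correlation. For this and every other list, the latter has too few residual degrees of freedom to decide on the call. The preset correlation of 0.01 takes genes as nearly independent, so the first adjusted p rests on the number of genes. Where members of a list vary together between libraries, it is too small. IFITM3 has close paralogs whose reads the counting could have split, so its level is uncertain. Between 30 and 35 members passed with any 1 library left out. Transcripts of the histone genes listed for non-polyadenylated RNA were higher in MCF7 too, in 8 of 14 measured members. The same held for members of the MHC class I, 17q23, 20q13 and p53 target lists. Without T47D library 2, the fold of IFITM3 was 84.6. The ratio of IFI44L was 235 (exact 95% interval 42.1 to 9294) without T47D library 2 and 733 (exact 95% interval 131 to 28976) without T47D library 1.

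MHC class I genes, which present antigen and are partly induced by interferon, had 7 of 14 members higher in MCF7, none lower and 7 that did not pass (8 adjusted over the list alone, of which 1 was higher in T47D, and with the library number as a block 9 higher in MCF7 and 1 in T47D). HLA-A averaged 2529 ± 1119.7 pseudo-counts in MCF7 and 435 ± 134 in T47D and lost its call without T47D library 1 (adjusted p = 0.053), and its closely related family members make its level uncertain. B2M, the light chain of class I molecules, was 3.09-fold higher (adjusted p = 0.011), a call lost without MCF7 library 1, MCF7 library 2 or T47D library 1 (adjusted p = 0.13, 0.079 and 0.091). NLRC5, a regulator of class I genes, was 3.33-fold higher (adjusted p = 0.013), a call lost without any 1 of the 4 libraries (adjusted p = 0.073 to 0.17). Camera gave adjusted p = 0.014 for this list and adjusted p = 0.66 with an estimated correlation. The set test fry, which does not compare with other genes, did not pass in 1 direction (adjusted p = 0.18). The list did not pass without MCF7 library 1 (adjusted p = 0.12) or without T47D library 1 (adjusted p = 0.098), and 0 to 4 of its members passed with 1 library left out. Of MHC class II genes, 4 were in the table, too few for the set test. HLA-DMA was 5.00-fold and CD74, the invariant chain gene, 5.64-fold lower in MCF7 (adjusted p = 0.0026 and 0.017), the other 2 did not pass and 2 passed when adjusted over the list alone. The call for HLA-DMA was lost without MCF7 library 2 or T47D library 2 (adjusted p = 0.052 and 0.051), and that for CD74 without MCF7 library 2, T47D library 1 or T47D library 2 (adjusted p = 0.086, 0.13 and 0.16). The fold of CD74 was 3.36 without MCF7 library 2 and 17.4 without MCF7 library 1.

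Genes from regions 17q23 and 20q13, which are known to be amplified in MCF7, were mostly higher there. In 17q23, 25 of 27 measured members were higher in MCF7, none was lower and 2 did not pass (26 adjusted over the list alone, and with the library number as a block 26 higher in MCF7 and 1 in T47D). PPM1D, a phosphatase gene that restrains p53 (ENSG00000170836), averaged 2926 ± 172 pseudo-counts in MCF7 and 117 ± 11.4 in T47D. BCAS3, TRIM37 and HEATR6 were 28.5-fold, 20.8-fold and 15.8-fold higher, with adjusted p = 8.7e-05, 7.1e-05 and 0.00011. In 20q13, 19 of 35 members were higher, 1 was lower and 15 did not pass (22 adjusted over the list alone, of which 2 were higher in T47D, and with the library number as a block 21 higher in MCF7 and 2 in T47D). The sulfatase gene SULF2 (ENSG00000196562) averaged 16248 ± 4156 pseudo-counts in MCF7 and 180.0 ± 4.91 in T47D. NCOA3, a coactivator of the estrogen receptor, was 12.1-fold higher, CYP24A1, a vitamin D hydroxylase gene, was 133-fold higher and PFDN4 was 13.5-fold higher. The exception was the potassium channel gene KCNB1, at 3.65 ± 0.235 pseudo-counts in MCF7 and 67.4 ± 31.0 in T47D (adjusted p = 0.0021). Camera gave adjusted p = 4.1e-15 for 17q23 and 5.4e-06 for 20q13, and adjusted p = 0.26 for each with an estimated correlation. With 1 library left out, 16 to 22 members passed in 17q23, where 16 was reached without MCF7 library 1, and 9 to 12 passed in 20q13. In region 9p21, chosen as one known to be deleted in MCF7, 3 of 7 members were lower in MCF7, 2 were higher and 2 did not pass (6 adjusted over the list alone), and camera did not pass (adjusted p = 0.18). The members that were lower were CDKN2A, MTAP and PTPLAD2, and the last had no reads in MCF7 and was at least 64.3-fold lower. CDKN2B, a CDK inhibitor gene, was 3.03-fold higher in MCF7 (adjusted p = 0.017), a call lost without any 1 of the 4 libraries (adjusted p = 0.079 to 0.20), and DMRTA1 was at least 26.9-fold higher. In MCF7, 32 reads of CDKN2A, 78 of MTAP, 128 of DMRTA1 and 712 of CDKN2B were recovered, so transcripts of the region as a whole were not missing from these libraries. With any 1 library left out, 4 members of the 9p21 list passed. The fold of CYP24A1 was 66.5 without MCF7 library 2, and that of PFDN4 was 20.9 without T47D library 1. Without T47D library 2, the ratio of reads of CYP24A1 was 202 (exact 95% interval 55.9 to 1670.3).

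Direct targets of p53 were higher in MCF7 for 14 of 38 members, lower for 2 and did not pass for 22 (18 adjusted over the list alone, 25 with the library number as a block, 21 higher in MCF7 and 4 in T47D). GDF15, a stress-induced cytokine gene, averaged 665 ± 227 pseudo-counts in MCF7 and 35.8 ± 5.38 in T47D. TP53I3 and FAS, a death receptor gene, were the members lower in MCF7, by 14.5-fold and 8.81-fold (adjusted p = 0.00068 and 0.00069). SULF2 and PPM1D, the members with the smallest p, also belong to the 20q13 and 17q23 lists. Camera gave adjusted p = 0.0089 for the p53 list and adjusted p = 0.53 with an estimated correlation, and 8 or 9 members passed with 1 library left out. Of the genes listed for non-polyadenylated RNA, 14 were measured, all of them histone genes. Of these, 8 were higher in MCF7, none was lower and 6 did not pass (9 adjusted over the list alone). HIST2H2BE averaged 1234 ± 450.4 pseudo-counts in MCF7 and 267 ± 8.47 in T47D, and HIST1H2AG had 412 reads in MCF7 and 1 in T47D, a ratio of 276 (exact 95% interval 49.3 to 10938). Camera gave adjusted p = 0.0059 and adjusted p = 0.56 with an estimated correlation, and 3 to 5 members passed with 1 library left out. By fry in 1 direction the histone list did not pass (adjusted p = 0.073). Histone genes are near-identical copies, so the split of reads among them is uncertain. The list was fixed as a sign of poly(A) selection, but whether the histone transcripts counted here lacked a poly(A) tail was not measured. Carry-over of RNA without a poly(A) tail that differs between preparations cannot be told apart here from a difference between the lines. The fold of TP53I3 was 8.91 without T47D library 2. The ratio of HIST1H2AG was 455 (exact 95% interval 80.3 to 18107) without MCF7 library 2.

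Of 14 measured androgen and apocrine genes, 7 were higher in T47D, none was higher in MCF7 and 7 did not pass (8 adjusted over the list alone, of which 1 was higher in MCF7). With the library number as a block, 7 were higher in T47D and 2 in MCF7. PIP, AZGP1 and ABCC11, named among the largest differences, belonged to this list, and CYP4X1, a cytochrome P450 gene, had 2 reads in MCF7 and 510 in T47D, a ratio of 380.3 (exact 95% interval 105 to 3149). Camera gave adjusted p = 0.0013 and adjusted p = 0.39 with an estimated correlation, and 6 to 8 members passed with 1 library left out. Imprinted genes were higher in T47D for 8 of 13 members and higher in MCF7 for 1, with 4 that did not pass (10 adjusted over the list alone, of which 2 were higher in MCF7). With the library number as a block, 2 imprinted genes were higher in MCF7 and 8 in T47D. Only 13 of 31 imprinted and 14 of 25 androgen and apocrine genes listed were in the table, so members silent in both lines may be missing. SNRPN had 1 read in MCF7 and 1529 in T47D, a ratio of 2280.3 (exact 95% interval 409 to 90124), with the overlapping SNURF not told apart from it. SGCE, a sarcoglycan gene, had 3 reads in MCF7 and 324 in T47D, a ratio of 161 (exact 95% interval 54.6 to 785), and the growth factor gene IGF2 was 10.1-fold higher in T47D. MEST was the member higher in MCF7, with 1596 reads against 2, a ratio of 535 (exact 95% interval 148 to 4422). Camera gave adjusted p = 0.018 and adjusted p = 0.53 with an estimated correlation, and 6 or 7 members passed with 1 library left out. Genes of the unfolded protein and amino acid stress response passed camera in the T47D direction (adjusted p = 0.034, and adjusted p = 0.56 with an estimated correlation). By fry in 1 direction the stress response list did not pass (adjusted p = 0.072). Of its 28 members, 4 were higher in T47D, 2 were higher in MCF7 and 22 did not pass (5 adjusted over the list alone, 18 with the library number as a block, 2 higher in MCF7 and 16 in T47D). The members higher in T47D included the serine synthesis enzymes PHGDH and PSAT1, at 3.36-fold and 10.2-fold, and SHMT2 at 2.29-fold. Those higher in MCF7 were VLDLR, a lipoprotein receptor gene, and PDIA6, a protein disulfide isomerase gene, at 3.26-fold and 2.22-fold. The call for PHGDH was lost without MCF7 library 1, T47D library 1 or T47D library 2 (adjusted p = 0.11, 0.12 and 0.17), that for PSAT1 without MCF7 library 2, T47D library 1 or T47D library 2 (adjusted p = 0.061, 0.095 and 0.064), and that for SHMT2 without MCF7 library 1, T47D library 1 or T47D library 2 (adjusted p = 0.20, 0.096 and 0.16). Those for VLDLR and PDIA6 were lost without any 1 of the 4 libraries, with adjusted p = 0.076 to 0.19 and 0.069 to 0.22, and 0 to 2 members of the list passed with 1 library left out. Without MCF7 library 1 or T47D library 1 the list itself did not pass (adjusted p = 0.12 and 0.098). Without MCF7 library 2, the fold was 6.20 for PSAT1 and 6.49 for PHGDH, and without MCF7 library 1 that of PSAT1 was 29.1. The ratio of CYP4X1 was 154 (exact 95% interval 27.4 to 6075) without MCF7 library 2 and 607 (exact 95% interval 108 to 24025) without MCF7 library 1, and that of MEST was 259.9 (exact 95% interval 46.6 to 10271) without T47D library 2 and 810.3 (exact 95% interval 145 to 32025) without T47D library 1. For SGCE it was 97.5 (exact 95% interval 17.4 to 3864) without MCF7 library 2 and 98.3 (exact 95% interval 31.7 to 493) without T47D library 2, and the fold of PIP was 1203 without MCF7 library 1.

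**Figure D2:**
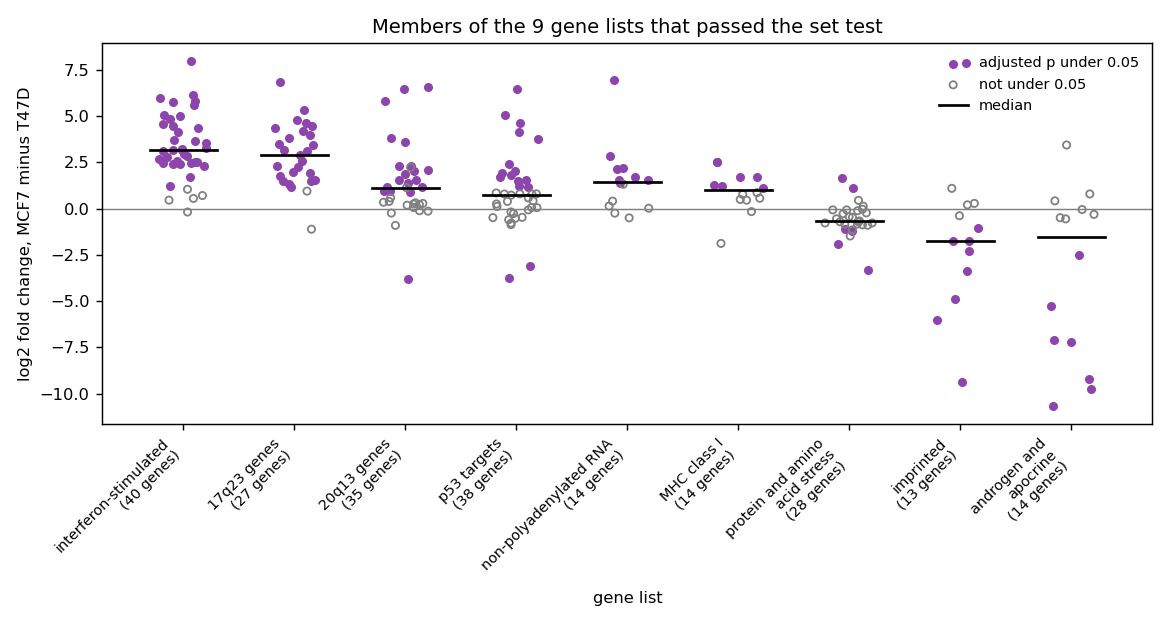
Log2 fold change (MCF7 minus T47D) on the vertical axis for each measured member of the 9 gene lists that passed camera with its preset correlation, with filled points for adjusted p under 0.05, open points for the rest and a bar at the median. Of the interferon-stimulated members 35 of 40 passed, all above 0, and the 7 androgen and apocrine members that passed lay below 0.

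The other 18 lists with at least 5 members did not pass camera, and many held members that differed strongly in opposite directions. Luminal identity genes were higher in MCF7 for 4 of 29, higher in T47D for 9 and did not pass for 16 (16 passed adjusted over the list alone, 6 to 10 with 1 library left out, camera adjusted p = 0.15). With the library number as a block, 7 luminal members were higher in MCF7 and 12 in T47D. TFF1, a classic estrogen-induced trefoil peptide, averaged 9395 ± 3763 pseudo-counts in MCF7 and 360.3 ± 65.3 in T47D, whereas the related TFF3 averaged 108 ± 47.3 pseudo-counts in MCF7 and 3076 ± 115 in T47D and the keratin gene KRT7 averaged 51.7 ± 19.1 pseudo-counts in MCF7 and 1522 ± 148 in T47D. ELF3, an epithelial transcription factor gene, was 3.66-fold higher in MCF7 (adjusted p = 0.0058), a call lost without MCF7 library 2, T47D library 1 or T47D library 2 (adjusted p = 0.091, 0.071 and 0.051). Without MCF7 library 1 the list passed camera in the T47D direction (adjusted p = 0.036). Of 40 estrogen-responsive genes, 11 were higher in MCF7, 10 were higher in T47D and 19 did not pass (23 adjusted over the list alone, 33 with the library number as a block, 16 higher in MCF7 and 17 in T47D, 8 to 14 with 1 library left out, camera adjusted p = 0.91). The median log2 fold change of the estrogen list was -0.41 and its mean was -0.04, with camera in the T47D direction and fry, which does not compare with other genes, in the MCF7 direction (adjusted p = 0.034). With the library number as a block, fry went in the T47D direction and did not pass (adjusted p = 0.13). WISP2 and RET, a receptor tyrosine kinase gene, were 15.7-fold and 10.1-fold higher in MCF7, while RAPGEFL1 was 4.61-fold lower. Of 19 progestin and glucocorticoid response genes, 3 were higher in MCF7, 7 were higher in T47D and 9 did not pass (13 adjusted over the list alone, 16 with the library number as a block, 8 higher in MCF7 and 8 in T47D, 6 to 7 with 1 library left out, camera adjusted p = 0.64). ELF5, a transcription factor of alveolar cells, averaged 14.96 ± 2.28 pseudo-counts in MCF7 and 539 ± 143 in T47D, and FKBP5, a chaperone gene induced by both receptors, was 4.01-fold lower in MCF7. NR3C1, the glucocorticoid receptor gene, was 5.95-fold higher in MCF7 (adjusted p = 0.0039), a call lost without MCF7 library 1 or T47D library 2 (adjusted p = 0.085 and 0.066). The median log2 fold change of that list was 0.27 and its mean was -0.45, with the test in the direction of the mean.

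HOX genes differed in 12 of 15 measured members, 5 higher in MCF7 and 7 higher in T47D (13 adjusted over the list alone, 7 to 10 with 1 library left out, camera adjusted p = 0.11). HOXC10 and HOXB2 averaged 101-fold and 144-fold more in T47D, HOXC4 and HOXB3 27.4-fold and 29.7-fold more. HOXA10 had no reads in T47D and was at least 43.7-fold higher in MCF7, and HOXA7 had 98 reads in MCF7 and 3 in T47D, a ratio of 21.9 (exact 95% interval 7.28 to 108). Of 42 germline genes listed, 5 were in the table and all 5 differed (5 adjusted over the list alone, camera adjusted p = 0.64), with 3 higher in MCF7 and 2 higher in T47D. The lowest mean of the higher line in the table was 15.3 pseudo-counts, so genes silent in both lines are absent. A difference was therefore likely in advance, and the 5 do not speak for the list. The same limit holds for HOX genes, of which 15 of 39 listed were in the table. It may also hold for imprinted (13 of 31), androgen and apocrine (14 of 25) and mesenchymal genes (9 of 25). Further such lists were the methylation-silenced tumour suppressors (16 of 39) and steroid and xenobiotic genes (18 of 33). PRAME averaged 2.74 ± 1.09 pseudo-counts in MCF7 and 1192 ± 162 in T47D, MAGEA1 had no reads in MCF7 and was at least 37.2-fold higher in T47D, TDRD1 was 82.5-fold higher in MCF7 and DDX43 was at least 27.3-fold higher there. MAGEA1 has near-identical relatives and is uncertain. Basal and myoepithelial markers were higher in MCF7 for 5 of 20 and higher in T47D for 6, with 9 that did not pass (11 adjusted over the list alone, 9 to 10 with 1 library left out, camera adjusted p = 0.64). With the library number as a block, 10 basal and myoepithelial members were higher in MCF7 and 6 in T47D. CAV1 and CAV2 had no reads in T47D, and the keratin genes KRT23 and KRT15 were 23.2-fold and 12.5-fold higher in T47D. Mesenchymal markers, which would mark another cell type, were higher in MCF7 for 2 of 9 and higher in T47D for 4, with 3 that did not pass (6 adjusted over the list alone, 2 to 4 with 1 library left out, camera adjusted p = 0.42). SNAI2 had no reads in T47D and was at least 20.6-fold higher in MCF7, and S100A4 was 13.9-fold higher in T47D. Blood and endothelial markers and ribosomal protein genes had 0 members in the table. The 47 ribosomal protein genes were listed as abundant transcripts, and how genes were chosen for the table is not stated. Absence from the table therefore does not show that a gene was not expressed, and this holds for the blood and endothelial markers too. The lower bound was 23.7 for MAGEA1 without T47D library 1 and 12.03 for SNAI2 without MCF7 library 2. Without MCF7 library 2, the ratio of reads of PRAME was 743 (exact 95% interval 133 to 29353), in place of a fold of 435.

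Epithelial junction genes were higher in T47D for 8 of 29 members, higher in MCF7 for 3 and did not pass for 18 (14 adjusted over the list alone, 18 with the library number as a block, 4 higher in MCF7 and 14 in T47D, 3 to 5 with 1 library left out, camera adjusted p = 0.076). CLDN1, a tight junction claudin gene (ENSG00000163347), averaged 34.2 ± 13.5 pseudo-counts in MCF7 and 14730.0 ± 6243 in T47D. ST14, the matriptase gene, was 6.01-fold and DSC2, a desmosomal cadherin gene, 5.14-fold higher in T47D. OVOL1, a transcription factor gene, was 3.40-fold higher in MCF7 (adjusted p = 0.0048), a call lost without MCF7 library 1 or MCF7 library 2 (adjusted p = 0.092 and 0.082). Without T47D library 1 the list passed camera in the T47D direction (adjusted p = 0.040). Cholesterol synthesis genes were higher in T47D for 7 of 23 members and higher in MCF7 for none, with 16 that did not pass (7 adjusted over the list alone, 15 with the library number as a block, 5 higher in MCF7 and 10 in T47D, 1 to 5 with 1 library left out, camera adjusted p = 0.13). MVK, the mevalonate kinase gene, was 3.46-fold higher in T47D (adjusted p = 0.0027), and FDFT1, the squalene synthase gene, was 3.01-fold higher (adjusted p = 0.0041), a call lost without MCF7 library 1 or MCF7 library 2 (adjusted p = 0.058 and 0.060). Without T47D library 1 this list also passed camera (adjusted p = 0.033). Receptor kinase and PI3K pathway genes were higher in MCF7 for 9 of 33 and higher in T47D for 7, with 17 that did not pass (19 adjusted over the list alone, 5 to 9 with 1 library left out, camera adjusted p = 0.76). MET, IGF1R and IRS1 were 40.3-fold, 4.19-fold and 4.50-fold higher in MCF7, while FGFR1 was 2.61-fold higher in T47D (adjusted p = 0.0086), a call lost without any 1 of the 4 libraries (adjusted p = 0.050 to 0.091). Without T47D library 2, the ratio of reads of MET was 102 (exact 95% interval 18.2 to 4026). With the library number as a block, 11 receptor kinase and PI3K pathway genes were higher in MCF7 and 11 in T47D. Of 23 caspase and BCL2 family genes, 8 were higher in MCF7, 3 were higher in T47D and 12 did not pass (13 adjusted over the list alone, 4 to 5 with 1 library left out, camera adjusted p = 0.13). BCL2L11, the pro-apoptotic BIM gene, was 13.7-fold higher in MCF7 and BCL2L1, the BCL-XL gene, was 3.97-fold higher in T47D.

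DNA methylation machinery was higher in MCF7 for 6 of 23 genes, higher in T47D for 1 and did not pass for 16 (7 adjusted over the list alone, 14 with the library number as a block, 9 higher in MCF7 and 5 in T47D, 1 to 4 with 1 library left out, camera adjusted p = 0.18). DNMT3A, a de novo DNA methyltransferase gene (ENSG00000119772), averaged 669.6 ± 53.8 pseudo-counts in MCF7 and 108 ± 6.24 in T47D (adjusted p = 0.00056). The maintenance methyltransferase gene DNMT1 averaged 2530.1 ± 109 pseudo-counts in MCF7 and 1754 ± 10.5 in T47D and did not pass (adjusted p = 0.15), while it passed with the library number as a block (adjusted p = 0.036). DNMT3B averaged 203 ± 49.6 pseudo-counts in MCF7 and 148 ± 22.0 in T47D (adjusted p = 0.37). TET2 and TET3, which oxidise methylated cytosine, were 3.86-fold and 2.73-fold higher in MCF7, and MECP2, a methyl-CpG binding protein gene, was 2.82-fold higher. ZBTB38 was 2.28-fold higher in T47D (adjusted p = 0.029). The call for TET2 was lost without MCF7 library 1 or T47D library 2 (adjusted p = 0.079 and 0.053), that for TET3 without MCF7 library 1, MCF7 library 2 or T47D library 2 (adjusted p = 0.12, 0.071 and 0.074), that for MECP2 without MCF7 library 1 or T47D library 2 (adjusted p = 0.087 and 0.060) and that for ZBTB38 without any 1 of the 4 libraries (adjusted p = 0.072 to 0.22). Of 16 tumour suppressor genes often silenced by promoter methylation, 2 were higher in MCF7, 3 were higher in T47D and 11 did not pass (5 adjusted over the list alone, 10 with the library number as a block, 5 higher in MCF7 and 5 in T47D, 2 to 3 with 1 library left out, camera adjusted p = 0.86). Apart from CDKN2A, they included TIMP3, a metalloproteinase inhibitor gene, at 1146 ± 626 pseudo-counts in MCF7 and 136 ± 44.3 in T47D, and the mismatch repair gene MLH1, which was 2.13-fold higher in T47D. The call for TIMP3 was lost without T47D library 2 (adjusted p = 0.053), and that for MLH1 without any 1 of the 4 libraries (adjusted p = 0.059 to 0.14). The median log2 fold change of that list was 0.25 and its mean was -0.086, with camera in the direction of the median and fry in that of the mean (adjusted p = 0.56). The fold of TIMP3 was 5.18 without MCF7 library 1, in place of 8.44.

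Proliferation genes were higher in T47D for 5 of 39 members, higher in MCF7 for 1 and did not pass for 33 (1 adjusted over the list alone, 0 to 1 with 1 library left out, camera adjusted p = 0.074). With the library number as a block, 19 members were higher in T47D and 4 in MCF7. CENPF, a kinetochore gene, was 3.11-fold higher in T47D (adjusted p = 0.0068) and MCM7, a replication licensing gene, was 2.09-fold higher in MCF7 (adjusted p = 0.040). The call for CENPF was lost without MCF7 library 1, MCF7 library 2 or T47D library 1 (adjusted p = 0.067, 0.092 and 0.055), and that for MCM7 without any 1 of the 4 libraries (adjusted p = 0.091 to 0.26). Without T47D library 1, when 0 members passed, the list passed camera in the T47D direction (adjusted p = 0.029). Regulators of G1 were higher in MCF7 for 4 of 17, higher in T47D for 2 and did not pass for 11 (9 adjusted over the list alone, 2 with 1 library left out, camera adjusted p = 0.46). CDK6, a cyclin D-dependent kinase gene, was 13.3-fold higher in MCF7 (adjusted p = 0.0016). Hypoxia and glycolysis genes were higher in MCF7 for 5 of 26, higher in T47D for 6 and did not pass for 15 (13 adjusted over the list alone, 18 with the library number as a block, 10 higher in MCF7 and 8 in T47D, 2 to 4 with 1 library left out, camera adjusted p = 0.69). NDRG1 was 6.68-fold higher in MCF7, and PFKFB3, a regulator of glycolysis, was 3.93-fold higher in T47D, a call lost without MCF7 library 1 or T47D library 2 (adjusted p = 0.088 and 0.098). Steroid and xenobiotic metabolism genes were higher in MCF7 for 5 of 18, higher in T47D for 2 and did not pass for 11 (7 adjusted over the list alone, 11 with the library number as a block, 6 higher in MCF7 and 5 in T47D, 3 to 5 with 1 library left out, camera adjusted p = 0.69). AKR1C2 had 341 reads in MCF7 and 1 in T47D and GSTT1 had 657 and 3, ratios of 229 (exact 95% interval 40.8 to 9058) and 147 (exact 95% interval 50.0 to 714), both uncertain because close paralogs exist. HSD17B8, a steroid dehydrogenase gene, was 3.94-fold higher in T47D (adjusted p = 0.0026), a call lost without MCF7 library 1 (adjusted p = 0.055). The median log2 fold change of that list was -0.29 and its mean was 0.92, with the test in the direction of the mean. The fold of CDK6 was 7.74 without MCF7 library 1. The ratio of AKR1C2 was 149.5 (exact 95% interval 25.5 to 6035) without MCF7 library 2.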

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

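Tests added after the data were seen were limma's voom with the library number as a block, and the blocked set tests with an estimated correlation or fry. The count of 3308 genes lay between 2735 and 3402 under 4 scalings, 2 filters, 2 pseudocounts and voom, and no call that passed there was in the other direction. With the library number as a block it was 5801, and with voom and the block 6290, where all 3308 genes passed again and the cause was not tested. The block leaves fewer residual degrees of freedom per gene than the main fit, yet its moderated degrees of freedom were 22.6, against 7.74. The blocked calls therefore rest mostly on spread borrowed from other genes. In the blocked voom fit all genes took their spread from 1 trend with read level. The count was 1298 without MCF7 library 1, 1458 without MCF7 library 2, 1614 without T47D library 1 and 1530 without T47D library 2, with the moderated degrees of freedom down from 7.74 to between 4.33 and 5.06. Camera passed 9 of 27 lists, and 8 to 10 with 1 library left out. It passed 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 0 with an estimated correlation in the blocked fit, where 0 did. With so few libraries the estimate leaves few residual degrees of freedom, and fewer still in the blocked fit. These failures were therefore close to fixed in advance and decide nothing about the lists. Fry passed 10 lists for balance in 1 direction and 27 for change in either direction. In the blocked fit fry passed 4 and 23, and camera passed the same 9. With a filter of 10 CPM in 2 libraries, camera passed 10 lists, without the stress response list and with the HOX and mesenchymal lists. With voom and the block it passed 11, without the stress response list and with the epithelial junction, HOX and luminal lists. Of 137 genes chosen by the naming rule that passed, 90 passed under every omission of 1 library. Under the other alternatives, calls were lost for CASP3 with total-only scaling and without the 20 most abundant genes in the totals, and for COL6A3 with voom, with no change of direction. The filter of 10 CPM in 2 libraries kept only 126 of the 137 genes, and the rest have no result there. The block ended no call among the 137 genes and added calls for ESR1 and DNMT1. The log2 fold change of ERBB2, -0.01 and not a call, was 0.0266 with total-only scaling, 0.00876 with upper-quartile scaling, 0.0215 without the 20 most abundant genes in the totals, and it ranged from -0.38 to 0.36 with 1 library left out, with 0.36 without MCF7 library 2 and 0.0485 without T47D library 1. That of GATA3, 0.32 and not a call, ranged from -0.0436 without MCF7 library 1 to 0.68 without MCF7 library 2, and the cause of these changes of sign was not tested. The median log2 fold change of all genes was 0.018 with the main scaling and 0.0061 to 0.055 with the other scalings. The planned count tests (quasi-likelihood, exact, Wald) and TMM factors were not run, neither on the deposited values, which are not counts, nor on the recovered reads, on which voom was the only test. Depth leaves the fold of genes without reads in a line as a lower bound, for 43 genes in MCF7 and 53 in T47D.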

Other observations

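The cross-line tests, and the zinc finger tests other than that of the neighbouring genes, were chosen or amended after the result was seen, and the zinc finger genes and region ends were picked from the data.

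Differences between the lines ran along the chromosomes. Of runs of 25 neighbouring genes in the table, the one from SUPT4H1 to TBX2, in the 17q23 region, had a median log2 fold change of 3.19, with 24 genes higher in MCF7 and 0 higher in T47D. Outside the fixed regions, the run from RBMX2 to MAP7D3 had a median of 1.68 (18 genes higher in MCF7), that from IL16 to MFGE8 1.67 (15 higher in MCF7 and 1 in T47D) and that from CHPF to SP100 1.64 (13 higher in MCF7). Runs higher in T47D went from EI24 to IGSF9B, with a median of -1.98 and 21 genes that passed, from C11orf1 to TAGLN (-1.86, 17 genes), from NLRX1 to ESAM (-1.58, 18 genes) and from PIGM to C1orf192 (-1.50, 19 genes). Runs were picked without shared genes, so neighbouring runs can be parts of a longer stretch. Those starting at C11orf1, NLRX1 and EI24 lie on the same chromosome arm and do not count as separate regions. The largest absolute median in 100 random gene orders was 1.38.

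Adjacent genes had log2 fold changes with a Pearson correlation of 0.228 across 11209 pairs, which are not independent, against a highest value of 0.0272 in 1000 random orders, which argues against a chance order. Reads shared between adjacent paralogs would be removed with pairs of the same symbol stem, yet the correlation without them was 0.210. The 17q23 and 20q13 regions alone are also too little, since the correlation was 0.222 without the chromosomes that hold them, where the highest random value was 0.0372. A hypothesis is that regional DNA dosage, or chromatin state, differs between the lines along regions other than 17q23 and 20q13 too. Neither was measured here, and DNA copy number and chromatin accessibility measured along the same regions in both lines would bear on it.

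Zinc finger genes by symbol, such as ZNF300, ZNF415, ZNF470 and ZFP28, were 15 of 131 genes (11.5%) with 3 or fewer reads in MCF7 and 2 of 164 (1.22%) in T47D, against 423 of all genes in the table (3.69%) (odds ratio between the lines 10.5, Fisher's exact p = 0.00019, two-sided). The class was picked from this contrast, so the odds ratio says nothing on reads shared between zinc finger paralogs, which stay open, while lower depth in MCF7 is excluded by its 1.43 times as many reads. Of 14 of these genes with a place in the gene order, 10 lie on chromosome 19. The 56 other genes next to them had a median log2 fold change of 0.17 (interquartile range -0.45 to 0.51), and 0 of them had 3 or fewer reads in MCF7, which argues against loss of a region that includes these neighbours, though a loss limited to zinc finger genes stays open. The class as a whole was not lower in MCF7 (53 genes higher in MCF7 and 42 in T47D), and silencing of single members is a hypothesis that was not tested and that promoter methylation of these genes in both lines would bear on.

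Genes abundant in either line often had a few reads in the other, mostly in library 2. Over 26 genes of MCF7 with at least 500 pseudo-counts there and under 1% of that in T47D, T47D library 2 held 0.606% of their MCF7 level and library 1 held 0.157%, and over 36 such genes of T47D, MCF7 library 2 held 0.445% and library 1 0.290%. Lower depth of library 1 would leave these pooled shares alike, but library 2 held 3.85 times the share of library 1 in T47D (95% interval 2.47 to 6.99 over 1000 resamples of the genes) and 1.53 times in MCF7 (1.27 to 2.66), where 3 genes held 75.8% of the reads in library 2. Reads assigned to the wrong library may contribute if the libraries numbered 2 shared a sequencing run, which no source used here states. That would make folds of such genes too small. The reads rose with the level in the other line (Spearman rho across genes 0.790 and 0.530, against 95th percentiles of 0.777 and 0.473 in 1000 shuffles). As the only source, wrongly assigned reads would give each gene the same share. The variance of the reads was 27.4 times that expected in MCF7 library 2, which argues against it there, and 2.83 times in T47D library 2, which leaves it open.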
